A study of Anthurium andraeanum with 18 samples.

How the data were processed

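The deposited table gives, for 18 leaf libraries and 158,487 assembled genes, an estimated count and a TPM per gene and library, with gene lengths of 201 to 16,384 bases (median 322) and text descriptions. Per the labels, the authors extracted RNA with Trizol, made Illumina libraries and trimmed adapters with cutadapt 1.9. The gene identifiers have the form that the de novo assembler Trinity writes, and the assembler settings and the quantifier are not given in the sources used here. The estimated count values were made by the authors from their reads per assembled gene and carry no normalisation. Between 89.8% and 96.7% of them per library are whole numbers within a tolerance of 1e-06. The TPM values, as deposited by the authors, are scaled by gene length and library. Their sums of 967,894 to 991,008 per library are the reason for reading the unlabelled columns as TPM. Of the genes, 39,888 carry a description (19,498 from Swiss-Prot, 39,509 from the nr database) and 118,599 carry none. Described genes have a median length of 811 bases and the others of 291. No genome sequence was used, so reads shared between fragments, alleles or paralogs of a gene could not be separated.

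Libraries were put into 6 groups of 3 by the material and temperature in their titles, and columns were matched to titles by library name. In MH the number in the library name differs from the replicate number of the title. Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the groups (min.count 10, min.total.count 15), which left 70,022 genes, 29,199 of them described. Libraries were scaled with TMM factors, which ran from 0.684 in Ken control to 1.54 in MH 40. 1 quasi-likelihood model with 6 group means and robust dispersion (12 residual degrees of freedom) gave all 11 comparisons: 3 within each material, 3 between materials at the same temperature, and the difference of the heat responses at 38/33 °C and at 40/35 °C. A gene was called at a Benjamini-Hochberg (BH) adjusted p below 0.05 over all tested genes. The common biological coefficient of variation was 0.39, and within groups it ran from 0.167 in Ken control to 0.537 in MH 38.

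Before the data were examined, 50 gene lists were fixed as text patterns on the descriptions, of which 14 were core lists for heat, photosynthesis, antioxidants, pigments and stress hormones. Each list with at least 5 tested members was tested with camera (limma 3.58.1) against the other described genes, with a preset inter-gene correlation of 0.01 and BH adjustment over the lists. The rule for named genes was also set before the data were examined. For the 4 comparisons of a heated group with its control it took, from each core list, the 2 called members with the smallest adjusted p whose libraries did not overlap between the groups, or the member with the highest level if none was called. For every comparison it took the 4 largest rises and 4 largest falls among called described genes that did not overlap and had a mean of at least 10 TPM in the higher group. This gave 132 genes. For the differences of responses, overlap was judged on the log2 CPM of each heated library minus the mean of its control. A fold against a group with no count in any library was computed against a floor of 3 counts per library and is written as at least that fold. No fold is given against a group with 1 to 3 counts in all.

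The pipeline was tested on simulated data, with 100 changed genes at each fold size among genes with the mean and dispersion of the real libraries. For Ken 38 against Ken control, with 60,392 genes in the step, 3% of 2-fold and 38% of 4-fold changes were recovered, and 6 of 47 calls were false. For MH 40 against MH control, with 60,748 genes, 2% and 33% were recovered, and 0 of 35 calls were false. With so few changed genes the p cutoff was stricter than in the real fits. Libraries held 15,845,190 to 22,867,268 counts.

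Alternatives set before the data were examined were DESeq2 1.42.0, RLE size factors in edgeR, no filter and a filter at 50 counts, a model of only the groups compared, the replicate number or library number as a block, each library left out, an adjusted p below 0.01 and a 2-fold minimum. For the lists they were an estimated correlation in camera, the fry test, and 1 entry per description. After seeing the data, further ones were added: library totals as the only scaling, TMM factors of the described genes, described genes only, all tested genes as background, accidental list members left out, and a term for animal-like transcripts. Other splits of the libraries into groups were refitted, all 10 for a pair of groups and 100 drawn with a fixed seed for results on both materials. Tables were read with pandas 2.3.3 and drawn with matplotlib 3.10.9 in Python 3.11.15.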

Results

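Leaf transcriptomes of Anthurium andraeanum were measured by RNA sequencing in 2 plant materials, called MH and Ken in the sample titles, at 3 temperature regimes. The sources used here do not say what MH and Ken are. Full-flowering plants stood in growth chambers with 12 h days and 12 h nights. Control plants stayed at 25 °C, and heated plants went through 3 days at 38/33 °C (day/night) and then 3 days at 40/35 °C, so the 40/35 °C samples had also passed through 38/33 °C. When the controls were sampled is not given, so plant age and time of day can differ between regimes and materials, which bears most on clock genes. Each of the 6 groups had 3 libraries, 18 in all, and the groups are called Ken control, Ken 38, Ken 40, MH control, MH 38 and MH 40. The titles call the replicates biological without saying that each was a separate plant, so the p-values measure the spread between these samples. Levels are TPM as mean ± SD (n = 3), and log2 changes are edgeR estimates ± SE. Rose, fell, higher and lower refer to an adjusted p below 0.05 in the edgeR quasi-likelihood test, and all p-values are adjusted by the Benjamini-Hochberg method (BH). TPM ratios differ from the fitted changes because the TMM factors differ between groups. Genes are assembled transcripts named by their deposited identifier, and several can be fragments of 1 gene. They carry no chromosome position here. In every pairwise comparison, each gene named from the largest changes or from the core gene lists had 3 libraries of 1 group above all 3 of the other, which chance alone gives in 10% of genes. After a gene list, the counts given as list alone are those adjusted over the list alone, without the other tested genes. Of all calls of gene lists made with camera, only those of transposable element proteins and of the list called viral in MH 40 against MH control and in MH 40 against Ken 40 held with an estimated correlation. Of the 929 entries of the viral list 874 are transposable element proteins too, so the 2 calls are largely 1. Lists follow text patterns: the HSP70 and HSP90 lists also hold partner proteins of these chaperones, and the HSP90 list 3 genes named after animal HSP90.

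Heat lowered transcripts of the photosynthetic apparatus in the leaf, and small heat shock proteins rose as a list except in MH 40. Genes of light harvesting and the photosystems summed to 111,410.0 ± 12,580.0 TPM in Ken control, 26,876 ± 2,724 in Ken 38 and 2,832 ± 136 in Ken 40. In MH the same sum was 155,090.0 ± 13,260.0 TPM in the control, 15,407 ± 19,410.0 at 38/33 °C and 1,822 ± 419 at 40/35 °C. Small heat shock proteins, which bind unfolding proteins, summed to 2,928 ± 1,253, 35,214 ± 2,076 and 52,343 ± 4,981 TPM in Ken control, Ken 38 and Ken 40. In MH control, MH 38 and MH 40 they summed to 7,989 ± 7,223, 33,547 ± 8,399 and 12,803 ± 6,881 TPM. Heated leaves also held more transcripts without any description: these took 9.43 ± 0.142% of the counts in Ken control, 13.998 ± 0.9999% in Ken 38 and 11.5 ± 0.215% in Ken 40. The MH shares were 8.74 ± 0.325%, 17.4 ± 0.722% and 21.5 ± 2.65%. In the principal component plot the first component held 47.7% of the variance and the second 20.5%. MH 38 replicate 3 stood apart from its group. On a scale from 0 for the MH control mean to 1 for the MH 40 mean it lay at 0.399, against 0.684 and 0.730 for replicates 1 and 2. MH control replicate 3 held 16,282 TPM of small heat shock proteins, against 4,609.9 and 3,075 in replicates 1 and 2.

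**Figure D1:**
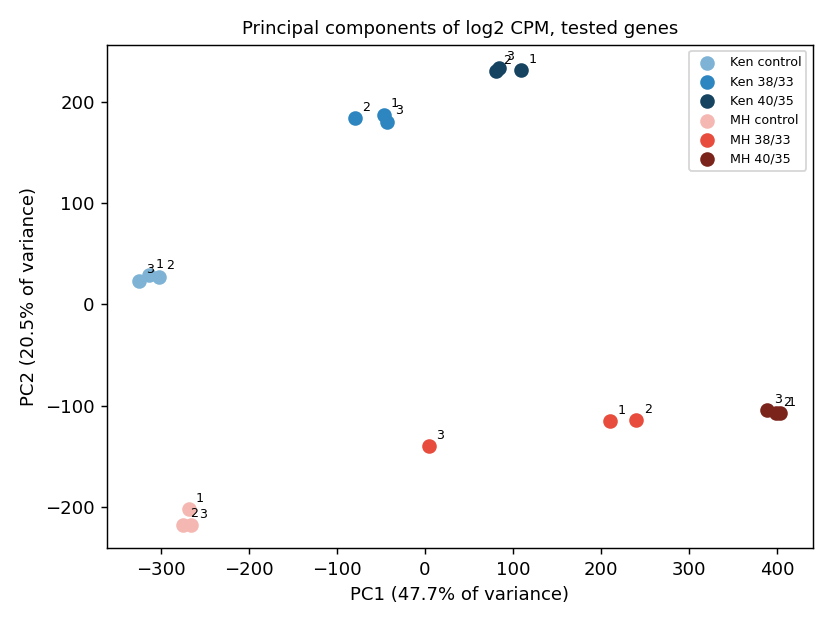
Principal components of log2 CPM of the tested genes, with component 1 on the x axis and component 2 on the y axis. Each point is 1 library, its colour gives the group and its number the replicate; component 1 holds 47.7% of the variance.

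**Figure D2:**
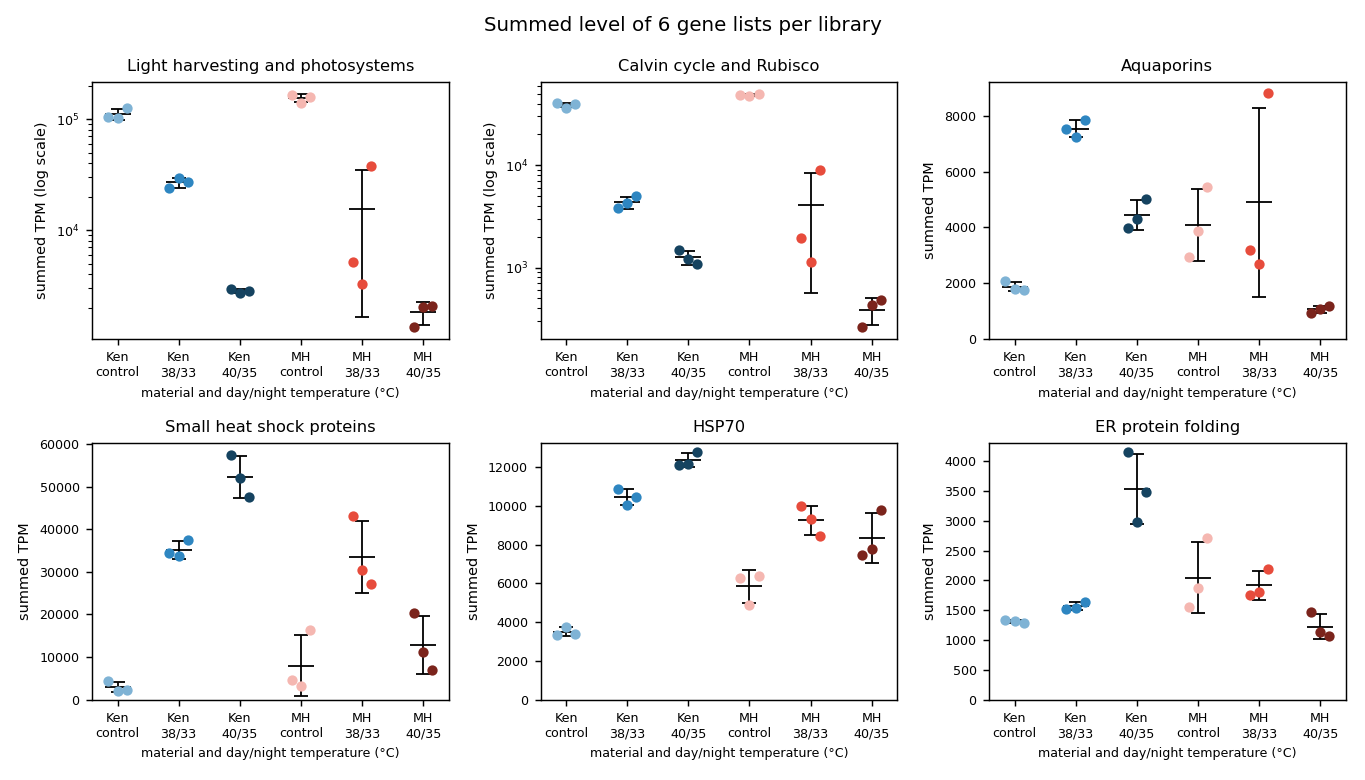
Summed TPM (y axis, a log scale for the light harvesting and Calvin cycle panels) of 6 gene lists in each group (x axis). Points are libraries and black bars are mean ± SD (n = 3), the lower bar of MH 38 on log scales being stopped short of 0; small heat shock proteins lie lower in MH 40 than in Ken 40.

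The median log2 change of all tested genes against the control was 0.42 in Ken 38, 0.30 in Ken 40, 0.73 in MH 38 and 1.03 in MH 40. For described genes alone it was -0.07, -0.10, -0.08 and -0.29, and list medians called relative are minus that of the described genes. With library totals as the only scaling the medians of all genes were 0.97, 0.76, 1.55 and 2.02.

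Ken 38 against Ken control asked what 3 days at 38/33 °C changed in Ken leaves. HSFB2A (TRINITY_DN39789_c1_g1), a heat stress transcription factor, rose from 1.15 ± 0.431 to 39.7 ± 3.14 TPM (log2 change 4.63 ± 0.30, adjusted p = 1.62e-10). The chaperones HSC-I (TRINITY_DN38156_c1_g1) and HSP70 (TRINITY_DN62961_c1_g1), cognates of HSP70, reached 1,724 ± 111 and 2,514 ± 88.1 TPM, from 403 ± 13.9 and 604 ± 71.2 in the control (adjusted p = 4.7e-09 and 3.09e-07). An (-)-alpha-terpineol synthase (TRINITY_DN52761_c0_g5), which makes a volatile monoterpene, fell from 2,347 ± 607 to 0.573 ± 0.272 TPM (log2 change -12.45 ± 0.93, adjusted p = 3.61e-07). HCF136 (TRINITY_DN55694_c3_g1), needed to assemble photosystem II, fell from 176 ± 15.4 to 27.1 ± 3.24 TPM (log2 change -3.28 ± 0.22, adjusted p = 1.07e-10).

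Among the 34 small heat shock proteins, 16 rose and 6 fell (list alone 17 and 6). The small heat shock protein list had a median log2 change of 1.52 or 1.18 with 0-count groups at their bound (relative 1.59) (camera adjusted p = 0.00118 and adjusted p = 0.619 with an estimated correlation). HSP17.4B (TRINITY_DN38803_c1_g1) went from 20.2 ± 7.04 to 265 ± 22.6 TPM (log2 change 3.38 ± 0.40, adjusted p = 1.07e-05), and HSP18.2 (TRINITY_DN55269_c1_g2) from 10.54 ± 1.67 to 44.3 ± 3.17. HSP70 and partner genes rose as a list (20 of 38 rose and 7 fell, list alone 20 and 7, camera adjusted p = 0.0019, adjusted p = 0.495 with an estimated correlation). In the HSP90 list 10 of 27 rose and 5 fell, list alone 12 and 5, median log2 0.51, adjusted p = 0.24 (camera). For heat shock transcription factors 7 of 23 rose and 4 fell, list alone 7 and 4, median log2 0.62, adjusted p = 0.193 (camera), with a heat shock factor-binding protein (TRINITY_DN38236_c1_g2) among the falls at 12.1 ± 1.998 TPM against 22.1 ± 2.82. In the HSP100 and Clp list 10 of 38 rose and 18 fell, list alone 12 and 18, median log2 -0.47, its sign turning to 0.11 with library totals alone, adjusted p = 0.281 (camera). Its named members CLPF (TRINITY_DN58713_c1_g1) and CLPS1 (TRINITY_DN47694_c2_g3), adapters of the chloroplast Clp protease, fell to 13.5 ± 3.73 and 18.8 ± 1.66 TPM from 130 ± 3.27 and 196 ± 19.3. Of genes for protein folding in the endoplasmic reticulum (ER), 6 of 28 rose and 13 fell, list alone 6 and 13, median log2 -0.45, its sign turning to 0.12 with library totals alone, adjusted p = 0.557 (camera). The disulfide isomerase PDIL1-5 (TRINITY_DN48590_c0_g1) rose to 14.4 ± 1.46 TPM from 1.37 ± 0.0404.

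Of all 76 light harvesting and photosystem genes, 1 rose and 44 fell (list alone 1 and 47). The light harvesting list had a median log2 change of -2.32 (relative -2.25) (camera adjusted p = 0.000157 and adjusted p = 0.663 with an estimated correlation). LHCA5 (TRINITY_DN46411_c0_g1), an antenna protein of photosystem I, went from 56.8 ± 3.52 to 11.9 ± 1.99 TPM (log2 change -2.67 ± 0.18, adjusted p = 1.54e-10). Calvin cycle and Rubisco genes fell as a list (2 of 18 rose and 12 fell, list alone 2 and 12, camera adjusted p = 0.00846, adjusted p = 0.593 with an estimated correlation). Rubisco activase RCA1 (TRINITY_DN55629_c0_g1) fell to 12.6 ± 1.99 TPM from 40.4 ± 1.46, while RBCS (TRINITY_DN32954_c0_g1), 1 of the Rubisco small chain genes, rose to 18.8 ± 1.69 from 0.417 ± 0.277. Antioxidant enzyme genes fell as a list (3 of 68 rose and 46 fell, list alone 4 and 49, camera adjusted p = 3.82e-07, adjusted p = 0.218 with an estimated correlation). SODCC.2 (TRINITY_DN48948_c1_g4), a superoxide dismutase, and the ascorbate peroxidase APX4 (TRINITY_DN52505_c0_g3) fell to 19.3 ± 0.957 and 17.9 ± 0.886 TPM from 103 ± 13.9 and 104 ± 11.6.

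Flavonoid and anthocyanin genes fell as a list (5 of 46 rose and 21 fell, list alone 5 and 23, camera adjusted p = 0.00846, adjusted p = 0.516 with an estimated correlation). LAR (TRINITY_DN50142_c0_g2), which feeds proanthocyanidins, fell from 53.7 ± 17.6 to 0.950 ± 0.123 TPM (log2 change -6.45 ± 0.49, adjusted p = 3.41e-08). Phenylpropanoid and lignin genes fell as a list (7 of 71 rose and 35 fell, list alone 8 and 39, camera adjusted p = 0.00268, adjusted p = 0.495 with an estimated correlation). Markers of xylem, a lignified tissue, fell as a list (0 of 17 rose and 9 fell, list alone 0 and 11, camera adjusted p = 0.00679, adjusted p = 0.495 with an estimated correlation). A cinnamoyl-CoA reductase-like SNL6 (TRINITY_DN60815_c0_g1) fell to 3.08 ± 1.33 TPM from 68.9 ± 27.8. Raffinose and trehalose genes rose as a list (16 of 36 rose and 9 fell, list alone 17 and 10, camera adjusted p = 0.019, adjusted p = 0.495 with an estimated correlation). RFS6 (TRINITY_DN56163_c0_g1), described as a raffinose-type galactosyltransferase, rose to 24.4 ± 5.06 TPM from 0.550 ± 0.147 (log2 change 4.90 ± 0.23, adjusted p = 8.76e-13), and the trehalose-phosphate synthase TPS9 (TRINITY_DN51233_c2_g6) rose to 26.01 ± 2.79 from 1.14 ± 0.176. For abscisic acid (ABA) genes 6 of 23 rose and 9 fell, list alone 6 and 10, median log2 -0.80, adjusted p = 0.788 (camera), with the ABA-responsive factors ABF4 (TRINITY_DN51406_c1_g2) and DPBF3 (TRINITY_DN40955_c2_g1) rising to 16.2 ± 1.55 and 55.9 ± 3.11 TPM from 2.28 ± 0.409 and 6.44 ± 0.510. With 6 of 25 clock entries, chloroplast translocases and tRNA enzymes, left out after the members were read, 8 of 19 clock genes rose and 4 fell (median log2 0.41, camera adjusted p = 0.281). GIGANTEA (TRINITY_DN63245_c1_g2) fell to 19.8 ± 0.706 TPM from 67.9 ± 14.3 and LHY (TRINITY_DN63222_c1_g3) rose to 114 ± 3.01 from 13.6 ± 3.58.

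The largest rises included 2 BURP domain proteins. RD22 (TRINITY_DN54005_c1_g3) rose from 0.450 ± 0.445 to 1,286 ± 365 TPM and BURP3 (TRINITY_DN48122_c2_g1) from 0.503 ± 0.325 to 1,571 ± 396 (adjusted p = 5.1e-05 and 4.09e-05, edgeR). The stem-specific protein TSJT1-like (TRINITY_DN41678_c0_g1) had no count in the control and was at least 257-fold higher, at 189 ± 79.0 TPM. Basic 7S globulin (TRINITY_DN35156_c1_g2) was at least 47.5-fold higher. Tricyclene synthase TPS4 (TRINITY_DN61283_c2_g1) fell from 653 ± 183 to 0.203 ± 0.0651 TPM. RL1 (TRINITY_DN35264_c3_g2) was at least 185-fold lower. In total 25,343 of 70,022 genes changed, 14,219 rose and 11,124 fell, 21,905 of them by at least 2-fold. The share of rises among called genes was 56.1% and 76.6% with library totals as the only scaling.

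**Figure D3:**
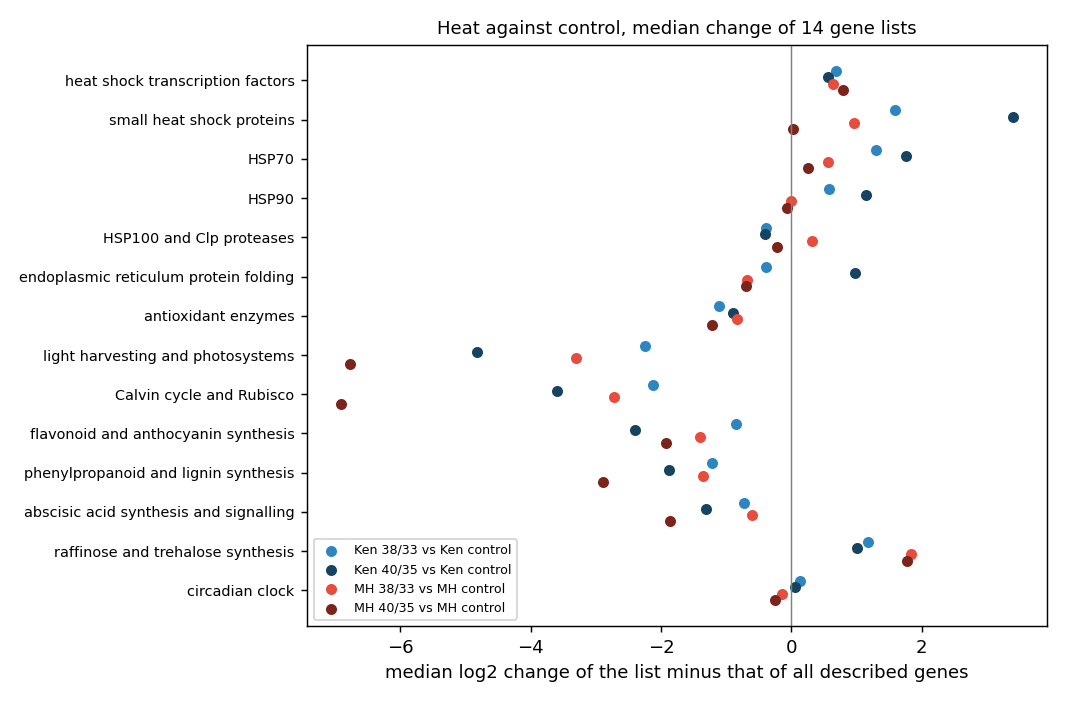
Median log2 change of the 14 core gene lists minus that of all described genes (x axis) for each list (y axis), 1 point per heat against control comparison. Calvin cycle and light harvesting genes lie furthest to the left, both in MH 40.

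Ken 40 against Ken control asked what the whole heat sequence changed in Ken. HSFB2A stood at 61.5 ± 17.2 TPM (log2 change 5.34 ± 0.31, adjusted p = 2.29e-11) and HSFA5 (TRINITY_DN45898_c0_g4), a further heat stress factor, at 48.3 ± 8.98 TPM against 4.51 ± 0.188 (log2 change 3.11 ± 0.25, adjusted p = 1.82e-09). HSP17.4B reached 502 ± 56.4 TPM (log2 change 4.40 ± 0.42, adjusted p = 9.16e-07). CRR6 (TRINITY_DN40355_c2_g6), needed for a chloroplast NADH dehydrogenase-like complex, had no count at 40/35 °C and was at least 472-fold lower, from 37.3 ± 1.70 TPM (adjusted p = 5.32e-05).

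Of 34 small heat shock proteins, 21 rose and 2 fell (list alone 22 and 2). Across the small heat shock protein members there was a median log2 change of 3.29 or 2.18 with 0-count groups at their bound (relative 3.40) (camera adjusted p = 1.77e-06 and adjusted p = 0.453 with an estimated correlation). HSP70 and partner genes rose as a list (25 of 38 rose and 3 fell, list alone 26 and 3, camera adjusted p = 6.38e-06, adjusted p = 0.413 with an estimated correlation). HSP90 and partner genes rose as a list (13 of 27 rose and 5 fell, list alone 13 and 5, camera adjusted p = 0.0118, adjusted p = 0.456 with an estimated correlation). The disulfide isomerase PDIL2-1 (TRINITY_DN50028_c0_g3) rose to 207 ± 15.9 TPM from 36.4 ± 2.56 (log2 change 2.03 ± 0.19, adjusted p = 1.47e-08). ER folding genes rose as a list (13 of 28 rose and 4 fell, list alone 13 and 5, camera adjusted p = 0.00751, adjusted p = 0.454 with an estimated correlation). Camera did not call heat shock transcription factors (10 rose and 4 fell of 23, adjusted p = 0.14), HSP100 and Clp genes (14 rose and 20 fell of 38, adjusted p = 0.456), ABA genes (8 rose and 11 fell of 23, adjusted p = 0.719) or clock genes (7 rose and 6 fell of the 19, adjusted p = 0.997).

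Among 76 light harvesting and photosystem genes, 1 rose and 59 fell (list alone 2 and 59). Across the light harvesting members there was a median log2 change of -4.93 (relative -4.82) (camera adjusted p = 4.8e-10 and adjusted p = 0.454 with an estimated correlation). Chlorophyll synthesis genes fell as a list (0 of 24 rose and 23 fell, list alone 1 and 23, camera adjusted p = 2.28e-06, adjusted p = 0.439 with an estimated correlation). Calvin cycle genes fell as a list (2 of 18 rose and 11 fell, list alone 2 and 11, camera adjusted p = 0.00474, adjusted p = 0.439 with an estimated correlation). Chloroplast superoxide dismutase SODCP (TRINITY_DN63358_c3_g1) fell to 6.05 ± 2.06 TPM, and catalase CATB (TRINITY_DN62244_c0_g2) to 3.24 ± 0.522 from 35.5 ± 4.30. Antioxidant genes fell as a list (10 of 68 rose and 37 fell, list alone 11 and 39, camera adjusted p = 0.00352, adjusted p = 0.413 with an estimated correlation).

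Flavonoid genes fell as a list (5 of 46 rose and 31 fell, list alone 5 and 32, camera adjusted p = 0.000164, adjusted p = 0.413 with an estimated correlation). Chalcone isomerase CHI (TRINITY_DN59794_c0_g1), an early enzyme of the pathway, stood at 12.6 ± 2.37 against 73.6 ± 16.4 TPM. Phenylpropanoid genes fell as a list (6 of 71 rose and 47 fell, list alone 7 and 48, camera adjusted p = 3.55e-05, adjusted p = 0.413 with an estimated correlation). Raffinose and trehalose genes rose as a list (18 of 36 rose and 9 fell, list alone 18 and 9, camera adjusted p = 0.0201, adjusted p = 0.413 with an estimated correlation). The ABA receptor PYL4 (TRINITY_DN58780_c2_g1) rose to 24.2 ± 11.6 TPM from 0.910 ± 0.236, and its other entry fell. GIGANTEA fell to 1.29 ± 0.337 TPM (log2 change -6.07 ± 0.26, adjusted p = 2.48e-13).

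Miraculin (TRINITY_DN49002_c0_g4), of a proteinase inhibitor family, was at least 574-fold higher at 87.3 ± 17.9 TPM, and Antimicrobial peptide 1 (TRINITY_DN29738_c0_g1) at least 165-fold higher. The falls to 0 counts included SBH1 (TRINITY_DN39093_c1_g1), a hydroxylase of sphingoid bases (at least 496-fold lower), PI21 (TRINITY_DN56240_c0_g5) (at least 369.9-fold lower) and the glycosyltransferase GAUT12 (TRINITY_DN36954_c0_g1) (at least 302-fold lower). Altogether 32,043 of 70,022 genes changed, 17,557 rose and 14,486 fell, 28,447 of them by at least 2-fold. Rises made up 54.8% of the calls, and 68.4% with library totals as the only scaling.

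Ken 40 against Ken 38 asked what the last 3 days added in Ken. ACO1 (TRINITY_DN53500_c1_g1), which carries out the last step of ethylene synthesis, rose from 1.55 ± 0.669 to 886 ± 152 TPM (log2 change 9.19 ± 0.98, adjusted p = 2.46e-05). The chitinase CHTB1 (TRINITY_DN42201_c0_g1) rose from 6.43 ± 1.98 to 1,033 ± 147 TPM, and VTE4 (TRINITY_DN61960_c0_g4), a methyltransferase of vitamin E synthesis, from 0.0367 ± 0.0404 to 40.3 ± 20.6. The antenna proteins LHCB3 (TRINITY_DN43846_c1_g3), CAB1 (TRINITY_DN52431_c4_g3) and CAB7 (TRINITY_DN62316_c1_g8) fell to 0.417 ± 0.0702, 0.603 ± 0.600 and 15.1 ± 5.10 TPM from 176 ± 2.94, 238 ± 27.8 and 4,601 ± 555 (adjusted p = 0.00058, 0.00202 and 0.00299, edgeR). Of the 76 light harvesting genes, 2 rose and 48 fell (list alone 2 and 50). Light harvesting genes as a list had a median log2 change of -2.20 (relative -2.18) (camera adjusted p = 1.16e-08 and adjusted p = 0.603 with an estimated correlation). Among the 34 small heat shock proteins, 12 rose and 0 fell (list alone 14 and 0). Small heat shock protein genes as a list had a median log2 change of 1.08 or 1.02 with 0-count groups at their bound (relative 1.10) (camera adjusted p = 0.00352 and adjusted p = 0.659 with an estimated correlation). HSP70 and partner genes rose as a list (16 of 38 rose and 3 fell, list alone 19 and 4, camera adjusted p = 0.00663, adjusted p = 0.501 with an estimated correlation). ER folding genes rose as a list (18 of 28 rose and 0 fell, list alone 20 and 0, camera adjusted p = 2.33e-05, adjusted p = 0.501 with an estimated correlation). PI21 was at least 18-fold lower. In total 21,372 of 70,022 genes changed, 9,996 rose and 11,376 fell, 17,819 of them by at least 2-fold.

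MH 38 against MH control asked the same of 3 days at 38/33 °C in MH. AS1 (TRINITY_DN36960_c2_g1), the enzyme that makes asparagine, rose from 0.210 ± 0.0954 to 556 ± 104 TPM (log2 change 10.63 ± 0.42, adjusted p = 3.54e-11). HSFB2A rose from 1.76 ± 0.722 to 46.1 ± 10.1 TPM (log2 change 3.99 ± 0.29, adjusted p = 1.27e-09) and HSFA3 (TRINITY_DN52649_c2_g1), a heat stress factor, from 10.3 ± 1.07 to 116 ± 13.1 (log2 change 3.06 ± 0.35, adjusted p = 4.57e-06). Mitochondrial HSP90-6 (TRINITY_DN56007_c0_g3) rose from 4.32 ± 0.385 to 43.4 ± 11.9 TPM (log2 change 2.55 ± 0.22, adjusted p = 7.73e-09). The antenna gene LHCA5 fell from 70.02 ± 3.03 to 18.7 ± 1.97 TPM (log2 change -2.72 ± 0.18, adjusted p = 2.02e-10).

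Heat shock transcription factors rose as a list (10 of 23 rose and 3 fell, list alone 12 and 3, camera adjusted p = 0.0179, adjusted p = 0.327 with an estimated correlation). Of all 34 small heat shock proteins, 12 rose and 3 fell (list alone 12 and 3). For the small heat shock protein list there was a median log2 change of 0.88 (relative 0.96) (camera adjusted p = 0.00938 and adjusted p = 0.717 with an estimated correlation). The 2 members named by rank were among the falls: the class I protein HSP18.1 (TRINITY_DN37313_c2_g1) at 31.2 ± 5.07 TPM against 47.3 ± 8.35 and the peroxisomal HSP16.0 (TRINITY_DN57909_c0_g2) at 88.2 ± 31 TPM against 130.4 ± 30.6. Without MH control replicate 3, 20 small heat shock proteins rose and 2 fell (camera adjusted p = 3.32e-05). In the HSP70 list 15 of 38 rose and 9 fell, list alone 15 and 9, median log2 0.47, adjusted p = 0.149 (camera), with HSC-I (TRINITY_DN38156_c1_g2) and HSP70 (TRINITY_DN49345_c0_g3) falling to 33.2 ± 16.4 and 70.8 ± 26.7 TPM from 106 ± 24.2 and 153 ± 13.5. Camera also did not call the HSP90 list (10 rose and 6 fell of 27, adjusted p = 0.119), HSP100 and Clp (15 rose and 15 fell of 38, adjusted p = 0.874), ABA (4 rose and 9 fell of 23, adjusted p = 0.233) or clock genes (6 rose and 5 fell of the 19, adjusted p = 0.841). ER folding genes did not pass: 3 of 28 rose and 16 fell, list alone 3 and 17, median log2 -0.77, its sign turning to 0.06 with library totals alone, adjusted p = 0.0622 (camera).

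Of 76 light harvesting and photosystem genes, 4 rose and 57 fell (list alone 4 and 58). For the light harvesting list there was a median log2 change of -3.39 (relative -3.31) (camera adjusted p = 9.24e-10 and adjusted p = 0.564 with an estimated correlation). Replicate 3 held 37,789.7 TPM of them, against 5,152 and 3,279 in replicates 1 and 2. Calvin cycle genes fell as a list (2 of 18 rose and 14 fell, list alone 2 and 14, camera adjusted p = 0.000515, adjusted p = 0.327 with an estimated correlation). Antioxidant enzyme genes fell as a list (4 of 68 rose and 42 fell, list alone 5 and 42, camera adjusted p = 4.54e-05, adjusted p = 0.192 with an estimated correlation). Superoxide dismutase SODCP (TRINITY_DN63358_c3_g1) fell to 20.4 ± 9.89 TPM from 274 ± 16.4. Raffinose and trehalose genes rose as a list (21 of 36 rose and 8 fell, list alone 21 and 10, camera adjusted p = 0.00177, adjusted p = 0.248 with an estimated correlation). Flavonoid genes fell as a list (5 of 46 rose and 26 fell, list alone 5 and 26, camera adjusted p = 0.00115, adjusted p = 0.327 with an estimated correlation). The dihydroflavonol reductase DFR (TRINITY_DN62946_c1_g4), a step towards anthocyanins, fell to 7.15 ± 1.75 TPM from 173 ± 81.1. Phenylpropanoid genes fell as a list (4 of 71 rose and 38 fell, list alone 5 and 39, camera adjusted p = 0.00137, adjusted p = 0.327 with an estimated correlation). CYP707A4 (TRINITY_DN38535_c0_g1), which breaks ABA down, fell to 0.870 ± 0.365 TPM from 11.2 ± 4.47, and the clock factor RVE8 (TRINITY_DN63484_c2_g1) to 5.55 ± 0.633 from 24.6 ± 7.72.

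The terpineol and tricyclene synthases named in Ken fell to 0.0300 ± 0.0361 and 0.0233 ± 0.0115 TPM from 49.0 ± 18.9 and 11.8 ± 5.66. Over all genes 33,225 of 70,022 genes changed, 21,104 rose and 12,121 fell, 29,498 of them by at least 2-fold. Rises were 63.5% of the calls and 85.2% with library totals only, and 40,338 genes were called without MH 38 replicate 3.

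MH 40 against MH control asked what the whole heat sequence changed in MH. The pectinesterase PME16 (TRINITY_DN59207_c0_g1) and the cell wall peroxidase PER64 (TRINITY_DN52644_c1_g1) lost every count, from 189.9 ± 93.6 and 163 ± 73.98 TPM, and were at least 1,975-fold and at least 1,408-fold lower (adjusted p = 4.91e-07 and 1.85e-05, edgeR). Transposon-derived genes were 3 of the 4 largest rises: a TNT 1-94 type polyprotein (TRINITY_DN40097_c2_g3), a gag protein (TRINITY_DN40663_c1_g6) and an RE1 type polyprotein (TRINITY_DN43870_c2_g3) were at least 196-fold, at least 139-fold and at least 119.7-fold higher. LHCA5 fell from 70.02 ± 3.03 to 5.07 ± 0.773 TPM (log2 change -4.64 ± 0.20, adjusted p = 9.29e-14). The small heat shock protein HSP18.2, which rose in Ken 40, fell from 34.8 ± 11.4 to 14.3 ± 2.87 TPM in MH 40 (log2 change -1.88 ± 0.22, adjusted p = 1.7e-07).

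For small heat shock proteins as a list 2 of 34 rose and 10 fell, list alone 1 and 9, median log2 -0.26, its sign turning to 0.75 with library totals alone and 0.28 with TMM factors of the described genes and 0.06 with RLE size factors, where the mean was -0.14 and the list test pointed up, adjusted p = 0.776 (camera). Without MH control replicate 3, 9 rose and 8 fell. The HSP70 list did not pass either: 12 of 38 rose and 11 fell, list alone 12 and 11, median log2 -0.03, its sign turning to 0.98 with library totals alone and 0.52 with TMM factors of the described genes and 0.30 with RLE size factors, where the mean was 0.04 and the list test pointed up, adjusted p = 0.675 (camera). HSP70 (TRINITY_DN49345_c0_g3) and HSP70 (TRINITY_DN39085_c1_g3) fell to 30.1 ± 10.6 and 18.6 ± 9.78 TPM from 153 ± 13.5 and 84.0 ± 14.3. Nor did camera call the HSP90 list (7 rose and 9 fell of 27, adjusted p = 0.592), heat shock transcription factors (10 rose and 5 fell of 23, adjusted p = 0.0671), HSP100 and Clp genes (13 rose and 17 fell of 38, adjusted p = 0.517), ABA genes (4 rose and 15 fell of 23, adjusted p = 0.1) or clock genes (5 rose and 12 fell of the 19, adjusted p = 0.351). HSFC2A (TRINITY_DN59997_c1_g1), a heat stress factor, fell to 11.1 ± 2.01 TPM from 52.5 ± 4.95. ER folding genes fell as a list (0 of 28 rose and 21 fell, the median being -0.98, its sign turning to 0.04 with library totals alone, list alone 0 and 21, camera adjusted p = 0.012, adjusted p = 0.459 with an estimated correlation).

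Among 76 light harvesting and photosystem genes, 3 rose and 64 fell (list alone 3 and 64). The light harvesting list had a median log2 change of -7.06 or -6.71 with 0-count groups at their bound (relative -6.78) (camera adjusted p = 1.84e-10 and adjusted p = 0.446 with an estimated correlation). Calvin cycle genes fell as a list (2 of 18 rose and 14 fell, list alone 2 and 14, camera adjusted p = 0.000693, adjusted p = 0.404 with an estimated correlation). Sedoheptulose bisphosphatase At3g55800 (TRINITY_DN34658_c2_g1) fell to 0.123 ± 0.1498 TPM from 9.60 ± 1.60. Antioxidant enzyme genes fell as a list (8 of 68 rose and 45 fell, list alone 8 and 45, camera adjusted p = 0.001, adjusted p = 0.313 with an estimated correlation). Flavonoid genes fell as a list (6 of 46 rose and 29 fell, list alone 6 and 29, camera adjusted p = 0.00668, adjusted p = 0.446 with an estimated correlation). DFR (TRINITY_DN62946_c1_g4) fell to 0.383 ± 0.0839 TPM and CHI to 5.09 ± 1.12, from 173 ± 81.1 and 73.6 ± 32.6. Phenylpropanoid genes fell as a list (12 of 71 rose and 51 fell, list alone 12 and 51, camera adjusted p = 0.000393, adjusted p = 0.313 with an estimated correlation). Raffinose and trehalose genes rose as a list (19 of 36 rose and 10 fell, list alone 20 and 10, camera adjusted p = 0.00668, adjusted p = 0.313 with an estimated correlation). The trehalose-phosphate synthases TPS9 and TPS8 (TRINITY_DN39583_c0_g2) rose to 21.7 ± 10.6 and 28.9 ± 11.3 TPM from 0.223 ± 0.0839 and 0.283 ± 0.0513.

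The ABA receptor PYL8 (TRINITY_DN54230_c0_g3) fell to 12.1 ± 2.36 TPM from 60.4 ± 11.7, and the clock gene LHY (TRINITY_DN55890_c0_g2) to 17.7 ± 7.42 from 58.7 ± 5.997. Cell wall modification genes fell as a list (20 of 166 rose and 113 fell, list alone 20 and 114, camera adjusted p = 1.75e-05, adjusted p = 0.313 with an estimated correlation). FLA13 (TRINITY_DN64022_c2_g6), an arabinogalactan protein, fell from 197 ± 29.9 to 0.0133 ± 0.0231 TPM, CYP94C1 (TRINITY_DN33312_c0_g2), an enzyme that oxidises jasmonate, was at least 1,021-fold lower, and ERF110 (TRINITY_DN50174_c0_g3), of the ethylene-responsive factors, was at least 83.4-fold higher. Of the 1,737 transposable element proteins, 1,109 rose and 101 fell (list alone 1,115 and 103). Their median log2 change was 2.64 or 2.16 with 0-count groups at their bound (relative 2.93) (camera adjusted p = 1.27e-18 and adjusted p = 0.0465 with an estimated correlation). In all 47,180 of 70,022 genes changed, 29,929 rose and 17,251 fell, 43,708 of them by at least 2-fold. Rises were 63.4% of the calls and 79.3% with library totals only.

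**Figure D4:**
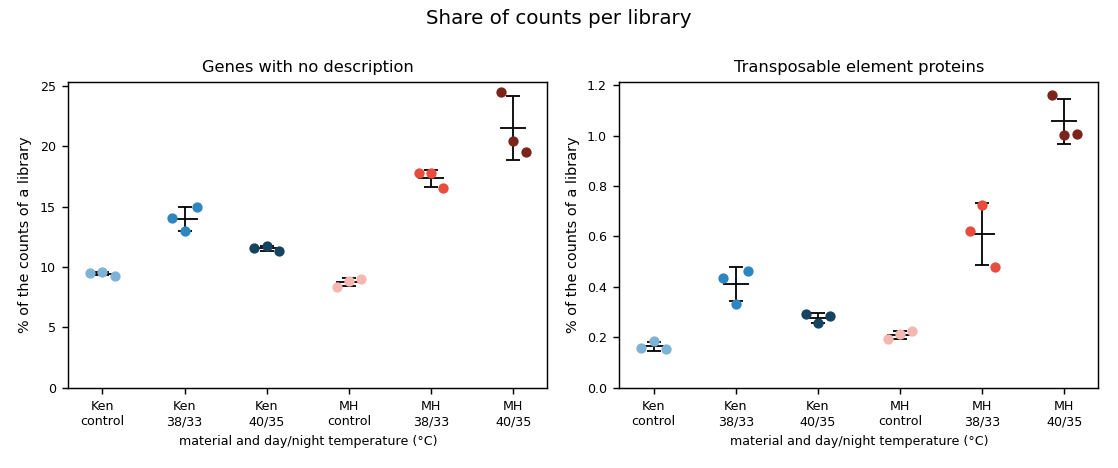
Percent of the counts of a library (y axis) taken by genes with no description (left) and by transposable element proteins (right) in each group (x axis). Points are libraries, bars are mean ± SD (n = 3), and MH 40 lies above MH control in both panels.

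MH 40 against MH 38 asked what the last 3 days added in MH. WRKY51 (TRINITY_DN39882_c2_g4), a stress-related WRKY factor, rose from 0.173 ± 0.219 to 15.6 ± 6.73 TPM (log2 change 6.52 ± 0.90, adjusted p = 2.52e-05), and an O-glucosyltransferase rumi-like gene (TRINITY_DN56857_c2_g2) was at least 109-fold higher. PME34 (TRINITY_DN59207_c0_g2), a pectinesterase, was at least 164-fold lower and a 21 kDa protein-like gene (TRINITY_DN41120_c0_g4) at least 129.9-fold lower. BURP3 (TRINITY_DN54005_c1_g1) fell from 428 ± 702 to 0.253 ± 0.143 TPM (log2 change -10.79 ± 1.89, adjusted p = 0.00135) and FLA13 from 35.2 ± 58.1 to 0.0133 ± 0.0231. MH 38 replicate 3 carries most of both and of PME34: without it the log2 changes are -6.59, -6.52 and -7.97. Among the 34 small heat shock proteins, 0 rose and 10 fell (list alone 0 and 14). The small heat shock protein list had a median log2 change of -1.31 (relative -1.09) (camera adjusted p = 0.00384 and adjusted p = 0.515 with an estimated correlation). Of all 76 light harvesting genes, 0 rose and 61 fell (list alone 1 and 64). Across the light harvesting members there was a median log2 change of -3.20 or -3.13 with 0-count groups at their bound (relative -2.98) (camera adjusted p = 1.61e-09 and adjusted p = 0.492 with an estimated correlation). By gene, 18,372 of 70,022 genes changed, 7,848 rose and 10,524 fell, 15,137 of them by at least 2-fold. Rises were 42.7% of the calls, 53.0% with library totals, 56.8% with RLE factors, 59.1% with TMM factors of the described genes and 57.3% in DESeq2. With the animal term, whose classes differ between groups, the count was 5,493.

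MH control against Ken control asked how the unheated materials differ. Of the 8 largest differences 4 were in genes named after disease resistance receptors. RPS2 (TRINITY_DN62041_c0_g1) and RPS2 (TRINITY_DN46653_c2_g6) had no count in MH and were at least 711-fold and at least 392-fold lower there (adjusted p = 3.13e-12 and 2.53e-08, edgeR). RPS2 (TRINITY_DN62509_c0_g1) and RGA1 (TRINITY_DN56547_c0_g2) stood at 201 ± 55.0 and 41.3 ± 3.70 TPM in MH and at 0.00667 ± 0.00577 and 0.00333 ± 0.00577 in Ken. LECCVA1 (TRINITY_DN31774_c0_g2), a mannose-binding lectin, and NCS2 (TRINITY_DN34934_c1_g4), named after an alkaloid synthesis enzyme, were at least 658-fold and at least 406-fold higher in MH. The receptor kinase At4g29180 (TRINITY_DN46232_c0_g4) and the zinc pump HMA2 (TRINITY_DN62013_c1_g7) were at least 570.1-fold and at least 469-fold lower.

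Cell wall modification genes were higher in MH as a list (53 of 166 were higher in MH and 11 lower, list alone 58 and 15, camera adjusted p = 4.46e-05, adjusted p = 0.827 with an estimated correlation). Of 34 small heat shock proteins, 14 were higher in MH and 5 lower (list alone 17 and 7). Their median log2 difference was 1.07 (relative 1.13) (camera adjusted p = 0.0412 and adjusted p = 0.898 with an estimated correlation). HSP70 and partner genes were higher in MH as a list (14 of 38 were higher in MH and 4 lower, list alone 16 and 5, camera adjusted p = 0.0191, adjusted p = 0.827 with an estimated correlation). Without MH control replicate 3, 10 small heat shock proteins were higher and 7 lower (camera adjusted p = 0.235), and 8 of the HSP70 list higher and 1 lower (adjusted p = 0.0724). The number of lists called then fell from 9 to 4. Together 15,276 of 70,022 genes differed, 7,102 higher in MH and 8,174 lower, 12,666 of them by at least 2-fold. The count was 3,422 with the animal term.

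MH 38 against Ken 38 asked how the heated leaves differ at 38/33 °C. ZSS1 (TRINITY_DN57290_c0_g2), a sesquiterpene synthase, was at least 1,221-fold higher in MH, at 71.2 ± 109.5 TPM, and CODM (TRINITY_DN48659_c1_g2), named after an alkaloid demethylase, at least 249-fold higher (adjusted p = 0.00313 and 8.63e-11, edgeR). MH 38 replicate 3 carries most of ZSS1: without it the fitted log2 difference is 11.43, against 14.74. RGA1 (TRINITY_DN56547_c0_g2) and RGA1 (TRINITY_DN38750_c4_g5), 2 resistance-type genes, were at least 1,129-fold and at least 531-fold higher. RPS2 (TRINITY_DN62041_c0_g1) and RPS2 (TRINITY_DN46653_c2_g6) were at least 1,525-fold and at least 1,084-fold lower, and At4g29180 at least 553-fold lower. Among 76 light harvesting genes, 6 were higher in MH and 7 lower (list alone 3 and 3). Light harvesting genes as a list had a median log2 difference of -0.90 (relative -0.87) (camera adjusted p = 0.000833 and adjusted p = 0.945 with an estimated correlation). Without MH 38 replicate 3 the light harvesting counts were 4 higher and 53 lower (camera adjusted p = 9.8e-11). Of the 1,737 transposable element proteins, 478 were higher in MH and 169 lower (list alone 492 and 172). Their median log2 difference was 0.85 or 0.70 with 0-count groups at their bound (relative 0.88) (camera adjusted p = 0.000575 and adjusted p = 0.945 with an estimated correlation). For small heat shock proteins 11 of 34 were higher in MH and 6 lower, list alone 12 and 6, median log2 0.18, adjusted p = 0.677 (camera). Among all genes 24,269 of 70,022 genes differed, 13,952 higher in MH and 10,317 lower, 20,838 of them by at least 2-fold. The animal term left 2,588 genes and, in camera, 0 lists (5 at an unadjusted p below 0.05). Higher genes were 57.5% of the calls and 71.7% with library totals only, and 32,703 genes were called without MH 38 replicate 3. The 4 lists called became 9 without that library and 2 without MH 38 replicate 2.

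MH 40 against Ken 40 asked the same after the 40/35 °C step. At4g29180 stood at 0.0133 ± 0.0231 against 99.0 ± 20.9 TPM, and RPS2 (TRINITY_DN62041_c0_g1) and the acylphosphatase acyP (TRINITY_DN33642_c0_g1) were at least 908-fold and at least 414-fold lower in MH. RGA1 (TRINITY_DN56547_c0_g2), the kinase Lr10 (TRINITY_DN56583_c1_g2), the F-box gene PP2B10 (TRINITY_DN53717_c1_g1) and the transposon polyprotein Tf2-12 (TRINITY_DN33849_c1_g5) were at least 578-fold, at least 165-fold, at least 182-fold and at least 284-fold higher (adjusted p = 3.18e-09, 4.74e-09, 4.79e-09 and 1.89e-06, edgeR). Among the 34 small heat shock proteins, 5 were higher in MH and 26 lower (list alone 5 and 27). Their median log2 difference was -2.07 (relative -1.79) (camera adjusted p = 0.00233 and adjusted p = 0.695 with an estimated correlation). HSP70 and partner genes were lower in MH as a list (2 of 38 were higher in MH and 27 lower, list alone 2 and 29, camera adjusted p = 0.00449, adjusted p = 0.494 with an estimated correlation). ER folding genes were lower in MH as a list (1 of 28 were higher in MH and 24 lower, list alone 1 and 25, camera adjusted p = 4.75e-05, adjusted p = 0.376 with an estimated correlation). Starch and sucrose genes were lower in MH as a list (1 of 79 were higher in MH and 55 lower, list alone 1 and 55, camera adjusted p = 4.64e-05, adjusted p = 0.139 with an estimated correlation). Of all 1,737 transposable element proteins, 809 were higher in MH and 89 lower (list alone 822 and 90). Their median log2 difference was 1.62 or 1.57 with 0-count groups at their bound (relative 1.91) (camera adjusted p = 6.64e-19 and adjusted p = 0.0397 with an estimated correlation). All told 33,973 of 70,022 genes differed, 19,765 higher in MH and 14,208 lower, 30,297 of them by at least 2-fold. With the animal term 13,726 were called. Higher genes were 58.2% of the calls, 75.9% with library totals and 70.9% with TMM factors of the described genes.

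A further comparison counted the genes that responded alike in both materials, whose controls are separate libraries. At 38/33 °C 8,004 genes rose in both and 7,347 fell in both, where independent responses would give 4,286 and 1,926. Another 759 were called in opposite directions, so 95.3% of genes called in both moved alike. At 40/35 °C 12,472 rose in both and 10,624 fell in both, against 7,504 and 3,569 for independent responses, and 1,682 were opposite (93.2% alike). HSFB2A (TRINITY_DN39789_c1_g1, not its other entry) and TPS9 rose and LHCA5, HCF136 and the SNL6-like reductase fell in all 4 heat against control comparisons.

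The difference of the responses at 38/33 °C, the MH change minus the Ken change, was tested as an interaction in edgeR. MYB114 (TRINITY_DN55582_c0_g2), named after a pigment-regulating MYB factor, went from 0.0867 ± 0.0808 to 54.6 ± 27.6 TPM in Ken and 0.837 ± 1.13 to 0.237 ± 0.410 in MH (log2 difference -12.16 ± 1.57, adjusted p = 0.000189). A thaumatin-like protein (TRINITY_DN61322_c2_g2), of a defence-related family, went from 68.3 ± 2.42 to 6.17 ± 2.21 TPM in Ken and 0.813 ± 0.762 to 54.1 ± 44.8 in MH (log2 difference 10.39 ± 1.51, adjusted p = 0.00102). The cytochrome P450 CYP71A1 (TRINITY_DN38332_c4_g2) and the demethylase JMJ25 (TRINITY_DN46947_c1_g2) had a higher change in MH, from 17.7 ± 2.75 to 0 ± 0 TPM in Ken and 12.4 ± 8.83 to 16.1 ± 3.56 in MH, and from 3.43 ± 0.737 to 9.08 ± 1.20 TPM in Ken and 0 ± 0 to 13.5 ± 6.66 in MH. The transporter ABCG5 (TRINITY_DN58596_c2_g3) went from 0.0367 ± 0.0153 to 1.42 ± 0.275 TPM in Ken and 22.7 ± 5.23 to 0.970 ± 1.26 in MH, and the protease Vignain (TRINITY_DN36799_c1_g2) from 0 ± 0 to 0.0800 ± 0.139 TPM in Ken and 40.04 ± 20.1 to 0.0833 ± 0.144 in MH.

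Of 76 light harvesting genes, 4 had a higher change in MH and 2 a lower one (list alone 2 and 1). For the light harvesting list there was a median log2 difference of -1.09 (relative -1.14) (camera adjusted p = 0.000269 and adjusted p = 0.687 with an estimated correlation). Without MH 38 replicate 3, 4 had a higher and 48 a lower change in MH (camera adjusted p = 1.19e-12). HSP100 and Clp genes had a higher change in MH as a list (10 of 38 had a higher change in MH and 2 a lower one, list alone 12 and 3, camera adjusted p = 0.0445, adjusted p = 0.687 with an estimated correlation). For small heat shock proteins 3 of 34 had a higher change in MH and 9 a lower one, list alone 5 and 9, median log2 -0.73, adjusted p = 0.181 (camera). Of 70,022 genes 7,591 differed in their response, 4,247 with a higher and 3,344 with a lower change in MH, 6,925 by at least 2-fold. The higher share was 55.9%, and 70.8% with library totals. Without MH 38 replicate 3 the count was 14,839, and without Ken 38 replicate 1 it was 5,024.

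At 40/35 °C the interaction was called for the lists of small heat shock proteins, HSP70, DnaJ and ER folding. Not called were the HSP90, HSP100 and Clp and chaperonin lists, whose single members can still differ. BURP3 (TRINITY_DN54005_c1_g1), a BURP domain protein, went from 7.38 ± 1.91 to 785 ± 152 TPM in Ken and 279 ± 247 to 0.253 ± 0.143 in MH (log2 difference -17.01 ± 2.41, adjusted p = 0.000303). NPF7.3 (TRINITY_DN48726_c2_g1), of a family with nitrate transporters, went from 0.143 ± 0.0702 to 42.3 ± 9.36 TPM in Ken and 3.20 ± 1.42 to 0.130 ± 0.0872 in MH (log2 difference -12.68 ± 1.06, adjusted p = 1.08e-06), and NPF7.1 (TRINITY_DN58460_c0_g3) from 0.370 ± 0.351 to 20.1 ± 5.995 TPM in Ken and 4.73 ± 0.537 to 0 ± 0 in MH. A 21 kDa protein (TRINITY_DN63355_c1_g1) went from 0.193 ± 0.301 to 88.2 ± 80.9 TPM in Ken and 8.80 ± 5.64 to 0.720 ± 0.376 in MH. A TIR-NBS-LRR resistance protein (TRINITY_DN40856_c0_g1) went from 0.0267 ± 0.0462 to 0 ± 0 TPM in Ken and 0 ± 0 to 13.8 ± 8.21 in MH (adjusted p = 0.0314). The other 3 of the largest positive differences, major urinary protein Mup3 (TRINITY_DN34435_c0_g1), alpha-1-antitrypsin Serpina1c (TRINITY_DN45529_c0_g1) and hemoglobin subunit HBA1 (TRINITY_DN32170_c0_g2), carry animal descriptions.

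Among 34 small heat shock proteins, 0 had a higher change in MH and 23 a lower one (list alone 2 and 24). For the small heat shock protein list there was a median log2 difference of -3.42 (relative -3.20) (camera adjusted p = 7.28e-06 and adjusted p = 0.501 with an estimated correlation). HSP70 and partner genes had a lower change in MH as a list (2 of 38 had a higher change in MH and 25 a lower one, list alone 2 and 28, camera adjusted p = 2.39e-05, adjusted p = 0.206 with an estimated correlation). ER folding genes had a lower change in MH as a list (1 of 28 had a higher change in MH and 22 a lower one, list alone 1 and 24, camera adjusted p = 5.64e-07, adjusted p = 0.191 with an estimated correlation). Control genes, often taken as steady, also had a lower change in MH as a list (median log2 difference -1.14, against -1.52 for the HSP70 list, camera adjusted p = 5.69e-05, adjusted p = 0.191 with an estimated correlation). Without MH control replicate 3 the counts were 0 higher and 22 lower for small heat shock proteins (median -2.74, camera adjusted p = 1.22e-05), 1 and 23 for HSP70, and 1 and 23 for ER folding. Of the 76 light harvesting genes, 2 had a higher change in MH and 11 a lower one (list alone 2 and 10). The light harvesting list had a median log2 difference of -1.11 (relative -0.89) (camera adjusted p = 0.0143 and adjusted p = 0.821 with an estimated correlation). Among the 1,737 transposable element proteins, 311 had a higher change in MH and 43 a lower one (list alone 305 and 43). For the transposable element list there was a median log2 difference of 1.48 (relative 1.70) (camera adjusted p = 1.14e-12 and adjusted p = 0.16 with an estimated correlation). Among 70,022 genes 14,987 differed in their response, 7,231 with a higher and 7,756 with a lower change in MH, 13,894 by at least 2-fold. The animal term left 8,097. Higher changes were 48.2% of these, 70.8% with library totals and 60.6% with TMM factors of the described genes.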

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

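The tests on transposable element proteins, vertebrate RNA and genomic DNA, on scaling and the MH control level of heat shock proteins, and on the vertebrate-like transcripts were chosen only after the result was seen. Those on undescribed genes and on random lists were added once the patterns were known, with their bounds written before the values they measure were seen, and the other splits of the libraries were set before the data were examined. Each result listed next was picked for passing the edgeR or camera test of the difference between the MH and Ken heat responses.

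At 38/33 °C 7,591 genes and 14 lists differed in response. The median log2 difference, MH minus Ken, was 0.61 for HSP100 and Clp genes, 0.48 for chaperonins, 0.46 for autophagy genes, 0.80 for organelle-encoded genes, -1.56 for class III peroxidases, -1.09 for light harvesting and -0.69 for chlorophyll synthesis. It was -0.99 for ethylene response factors (ERF), -0.59 for auxin response, -1.13 for pathogenesis-related proteins (-0.39 and not called, adjusted p = 0.157, without 444 disease resistance entries), -1.62 for dehydrins, -0.62 for cell wall modification, -0.88 for guard cell markers and -0.74 for flower organ markers. The named genes had edgeR adjusted p-values of 0.00102 for the thaumatin-like protein, 0.0412 for GAUT12, 6.2e-05 for CYP71A1, 9.22e-05 for JMJ25, 0.000189 for MYB114, 0.00929 for the TSJT1-like protein, 0.0405 for Vignain and 0.00357 for ABCG5.

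At 40/35 °C 14,987 genes and 22 lists differed in response. The median log2 difference was -3.42 for small heat shock proteins, -1.52 for HSP70, -0.53 for DnaJ proteins and -2.06 for ER folding. It was -4.22 for class III peroxidases, near PER54 at -4.32, whose size rests on 0 TPM in Ken. It was -1.11 for light harvesting, -2.15 for the Calvin cycle and -0.99 for chlorophyll breakdown. For hormones and metabolism it was -1.64 for ABA, -1.23 for ethylene, -1.20 for ERF, -0.79 for starch and sucrose, -2.61 for aquaporins, -1.51 for the cell wall, -1.48 for the cuticle and -2.02 for desaturases. Further medians were -0.76 for ribosomal proteins, -0.43 for splicing factors (turning to 0.09 with library totals alone), 1.48 for transposable element proteins, -1.002 for flower organ markers, 1.28 for the viral list (0.78 over the 55 entries that are not transposable element proteins) and -1.14 for control genes. These named genes had edgeR adjusted p-values of 0.0182 for Mup3, 0.0302 for Serpina1c, 0.0314 for the TIR-NBS-LRR protein, 0.00692 for HBA1, 0.000303 for BURP3, 9.25e-06 for NPF7.1, 1.08e-06 for NPF7.3 and 0.000302 for the 21 kDa protein.

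Transposable element proteins and undescribed genes were higher in heat, most of all in MH 40. If the loss of abundant transcripts had only shifted all shares, genes of like level would move alike, but the median log2 change of transposable element proteins lay 1.51 above that of level-matched described genes (1.34 to 1.57 with single libraries left out), which argues against it as the whole cause, although those genes had a median of 1.14 themselves. For undescribed genes the gap was 0.64 (0.55 to 0.66), and that range reaches below the bound of 0.58, so the same cause cannot be told apart for them. Vertebrate RNA is argued against because the MH 40 library with the fewest vertebrate-like counts (11.5 CPM) held 24.5% undescribed counts, against at most 9.004% in MH control. Genomic DNA stays open: organelle-encoded genes changed by a median log2 of -1.40 in MH 40, but their high starting level would hide a small share of DNA, and an untested response to heat or difference between the materials may add to the pattern.

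Small heat shock protein, HSP70 and ER folding lists were called higher by camera in Ken 40 and not in MH 40. For small heat shock proteins scaling is argued against as the cause: the median log2 difference of the responses was -3.42, -3.27 with RLE factors, -3.12 with TMM factors of described genes, -3.16 in DESeq2 and, nearest to 0, -2.87 with library totals. A general loss of described transcripts of that level is argued against for them as the whole cause. The 10,000 random level-matched lists had a median of -0.48 (lowest -1.35), and 0 were as low as -3.42. Those lists hold genes drawn singly, without the correlation between related genes, so the count of 0 does not measure chance. HSP70 at -1.52 lies close to the lowest of its random lists (-1.44). The control genes at -1.14 also lie below the 2.5th percentile of the HSP70 random lists (-0.92). The higher level in the MH controls does not account for the difference in small heat shock proteins either. The heated leaves themselves differed, with a median log2 difference of -2.07 between MH 40 and Ken 40. A biological difference between MH and Ken in their response to heat may underlie the pattern, a hypothesis found and tested on the same data, and the labels give no state of the leaf at sampling.

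Vertebrate-like transcripts were abundant in some libraries and nearly absent from others of the same group. Plant genes named after vertebrate relatives are argued against: the summed share of 69 rodent-like genes differed 20.1-fold between the highest and lowest MH 40 replicate, against at most 2.96-fold in random described gene sets of that size. Whether vertebrate RNA or reads were carried in stays open. Of 36 rodent-like genes 21 were higher in each of 5 libraries than in any other, but those libraries were picked by the same class of genes. No biological explanation was tested.

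Refits of the 6 libraries of each pair of groups gave 10 splits per pair, too few for a share under 0.05. In gene calls only 1 of 10 splits, the real one, gave as many genes in any pair, and no other split gave a single gene (highest 0). The real counts were 28,013 for Ken 38 against control, 28,710 for Ken 40 against control, 25,448 for Ken 40 against Ken 38, 20,150 for MH 38 against control, 41,240 for MH 40 against control, 12,842 for MH 40 against MH 38, 16,115 for the 2 controls, 16,273 for MH 38 against Ken 38 and 33,511 for MH 40 against Ken 40. For calls of lists the number of the 10 splits with as many, then the real count and the highest other, were 1, 21 and 16 for Ken 38 against control, 1, 23 and 18 for Ken 40 against control, 2, 18 and 19 for Ken 40 against Ken 38, 3, 18 and 25 for MH 38 against control, 4, 21 and 25 for MH 40 against control, 1, 26 and 17 for MH 40 against MH 38, 6, 9 and 14 for the 2 controls, 6, 6 and 17 for MH 38 against Ken 38 and 2, 17 and 19 for MH 40 against Ken 40.

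For results on both materials 100 labellings, each a split within each material, were drawn, the real one included. As many genes with different responses as in the real one came from 3 at 38/33 °C (real 7,308, highest other 10,246) and 5 at 40/35 °C (17,089 and 21,906), and as many genes called alike from 1 at 38/33 °C (14,577 and 2) and 1 at 40/35 °C (24,280 and 0). These counts do not decide about chance, because mixing heated and control libraries removes the heat calls of a material, and the labellings above the real counts left 1 material split by heat. Chance cannot be excluded for the number of lists with different responses, where 66 labellings gave as many as 12 at 38/33 °C (highest other 23) and 31 as many as 20 at 40/35 °C (highest other 24).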

How the results depend on the processing

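Alternatives with library totals, TMM factors of described genes, described genes only, all genes as background, accidental members left out or a term for animal-like transcripts were chosen only after the result was seen; the others were set before. Over all alternatives, 168 of 191 counts of called genes, 119 of 155 counts of called lists and 45 of 48 counts of genes called alike stayed within 1.5 times the value reported. Of 3,375 refits of named genes 3,299 kept direction and call, 75 kept direction without passing, and 1 turned: Serpina1c (TRINITY_DN45529_c0_g1) had a log2 difference of -2.96 in its response at 40/35 °C with the animal term, whose classes follow such transcripts by construction. Choices for normalised values, such as a pseudocount, quantile scaling or a limma trend, were not run because counts were available. Most simulated 2-fold changes were not recovered. Causes other than fewer genes or samples were not tested. Only MH libraries lack an animal class, so that term overlaps with material.

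With described genes only, which are fewer, the calls were 14,665 for Ken 38 against control, 16,922 for Ken 40 against control, 12,939 for Ken 40 against Ken 38, 16,189 for MH 38 against control, 21,201 for MH 40 against control, 11,356 for MH 40 against MH 38, 8,364 for the 2 controls, 11,242 for MH 38 against Ken 38, 15,659 for MH 40 against Ken 40 and 9,654 for the response difference at 40/35 °C. With the animal term the calls were 5,493 for MH 40 against MH 38, 3,422 for the 2 controls, 2,588 for MH 38 against Ken 38, 13,726 for MH 40 against Ken 40 and 8,097 for the response difference at 40/35 °C. A filter at 50 counts gave 27,935 for MH 40 against control and 21,878 for MH 40 against Ken 40, a model of only the groups compared 20,150 for MH 38 against control, and DESeq2 11,554 for the response difference at 38/33 °C. Genes called alike in both materials were 9,747 at 38/33 °C with an adjusted p below 0.01, and with described genes only 9,158 at 38/33 °C and 12,372 at 40/35 °C.

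The replicate numbers do not pair the libraries: correlations between libraries of different groups, after each group mean was removed, ran from -0.117 to 0.105, and libraries did not correlate best with their own number throughout. With the replicate block 23,223 genes were called in Ken 38 against control, and all counts stayed within 1.5 times. With the library number as the block in MH, calls were 29,348 for MH 40 against control and 10,943 for MH 40 against MH 38.

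With an estimated correlation camera called 2 lists, the transposable element proteins and the viral list that mostly repeats them, in MH 40 against control and in MH 40 against Ken 40, and 0 lists in each of the other 9 comparisons. At an unadjusted p below 0.05 it gave, in those 9, 5 for Ken 38 against control, 4 for Ken 40 against control, 3 for Ken 40 against Ken 38, 7 for MH 38 against control, 3 for MH 40 against MH 38, 1 for the 2 controls, 0 for MH 38 against Ken 38, 2 for the response difference at 38/33 °C and 9 for the response difference at 40/35 °C of the 50 lists. The fry test gave 39 for Ken 38 against control, 43 for Ken 40 against control, 34 for Ken 40 against Ken 38, 39 for MH 38 against control, 47 for MH 40 against control, 42 for MH 40 against MH 38, 21 for the 2 controls, 18 for MH 38 against Ken 38, 40 for MH 40 against Ken 40, 16 for the response difference at 38/33 °C and 33 for the response difference at 40/35 °C. All tested genes as background gave 31 for Ken 38 against control, 36 for MH 38 against control, 41 for MH 40 against control, 41 for MH 40 against MH 38, 9 for MH 38 against Ken 38, 39 for MH 40 against Ken 40 and 40 for the response difference at 40/35 °C. 1 entry per description gave 11 for Ken 40 against Ken 38, 1 for MH 38 against Ken 38, 6 for the response difference at 38/33 °C and 12 for the response difference at 40/35 °C. In MH 38 against Ken 38 the animal term left 0 lists in camera (5 at an unadjusted p below 0.05) and the removal of accidental members left 2.

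With single libraries left out, called genes ranged over 19,917 to 21,983 for Ken 38 against control, 27,121 to 29,194 for Ken 40 against control, 15,621 to 17,366 for Ken 40 against Ken 38, 26,256 to 40,338 for MH 38 against control, 46,681 to 48,797 for MH 40 against control, 12,348 to 18,600 for MH 40 against MH 38, 11,279 to 12,929 for the 2 controls, 17,610 to 32,703 for MH 38 against Ken 38, 30,064 to 31,864 for MH 40 against Ken 40, 5,024 to 14,839 for the response difference at 38/33 °C and 11,972 to 13,582 for the response difference at 40/35 °C. Called lists ranged over 19 to 22 for Ken 38 against control, 24 to 25 for Ken 40 against control, 15 to 19 for Ken 40 against Ken 38, 16 to 21 for MH 38 against control, 21 to 24 for MH 40 against control, 16 to 26 for MH 40 against MH 38, 4 to 11 for the 2 controls, 2 to 9 for MH 38 against Ken 38, 15 to 20 for MH 40 against Ken 40, 10 to 17 for the response difference at 38/33 °C and 20 to 23 for the response difference at 40/35 °C. Genes called alike ranged over 12,693 to 15,709 at 38/33 °C and 19,556 to 22,203 at 40/35 °C. The libraries that moved a count by over 1.5 times were MH 38 replicate 3 (14,839 genes) and Ken 38 replicate 1 (5,024 genes) for the response difference at 38/33 °C, MH control replicate 3 (4 lists) for the controls, and MH 38 replicates 2 and 3 (2 and 9 lists) for MH 38 against Ken 38.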

Other observations

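Other gene groups fixed before the data were examined moved with heat. Ribosomal proteins fell as a list in Ken 38, with 15 rising and 219 falling of 378 (list alone 15 and 226, camera adjusted p = 9.88e-08, adjusted p = 0.619 with an estimated correlation). Unscaled, their share of counts was 2.44 ± 0.23%, 2.24 ± 0.07% and 2.58 ± 0.12% in Ken control, Ken 38 and Ken 40. Desaturases, most of them fatty acid enzymes that set how fluid membranes are but with a carotenoid and a sterol enzyme among the falls, fell as a list in MH 40, with 0 rising and 18 falling of 23 (list alone 0 and 18, camera adjusted p = 6.14e-05, adjusted p = 0.169 with an estimated correlation). Dehydrins and related proteins rose as a list in Ken 38, with 6 rising and 0 falling of 9 (list alone 6 and 0, camera adjusted p = 0.00159, adjusted p = 0.218 with an estimated correlation).

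Pathogenesis-related proteins, most of them described as disease resistance proteins, rose as a list in Ken 38, with 157 rising and 57 falling of 517 (list alone 163 and 58, camera adjusted p = 0.000551, adjusted p = 0.619 with an estimated correlation). They fell as a list in Ken 40, with 41 rising and 249 falling of 517 (list alone 43 and 257, camera adjusted p = 0.000795, adjusted p = 0.614 with an estimated correlation). Neither call stands without the 444 disease resistance entries: 14 of 73 rose and 23 fell in Ken 38 (median log2 -0.38, camera adjusted p = 0.675), and 14 rose and 37 fell in Ken 40 (adjusted p = 0.227).

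The following transcript groups were chosen after their values were seen, and levels are in CPM. The 69 rodent-like genes stood at 112 and 108 CPM in Ken control replicates 1 and 3, 75.4 in Ken 38 replicate 1, 175 and 192 in MH 40 replicates 2 and 3, and at most 15.5 elsewhere. The 116 primate-like genes stood at 23.2 CPM in Ken control replicate 2, 27.2 and 31.7 in Ken 38 replicates 2 and 3, 38.05, 41.9 and 218 in Ken 40, and at most 13.5 elsewhere. By a threshold of 20 CPM 5 libraries were rodent-like, 6 primate-like and 7 neither. Transcripts like those of Shallot virus X (22 genes) reached 77.2 CPM in Ken 38 replicate 1 and at most 0.175 elsewhere. Those like Commelina yellow mottle virus (51 genes) ran from 512 to 705 CPM in Ken control, 96.0 to 257 in heated Ken, 44.9 to 55.9 in MH control and 175 to 318 in heated MH. The 6 genes described as TAR1, encoded within ribosomal RNA genes in yeast, reached 6,492 CPM in Ken 38 replicate 2 and at most 1,866 elsewhere.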
